A study of Mus musculus with 21 samples.

How the data were processed

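The glucocorticoid receptor (GR), a nuclear receptor that binds DNA when it holds a glucocorticoid, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in livers of C57BL/6J mice. Per the labels' protocols, mice stayed at 21% oxygen (normoxia) or were kept at 7% oxygen for 6 h or 24 h, and then received dexamethasone (DEX, a synthetic glucocorticoid, 10 mg/kg, injected into the abdomen) or phosphate-buffered saline (PBS) 2 h before sampling. This gave 6 groups of 3 libraries, which the series' design text names as biological replicates, and an input control for each oxygen condition. Samples were put into groups by their titles. The 18 GR libraries each had a peak list. The 3 inputs were not analysed here as samples and entered only through the values the peak caller took from them.

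Reads were trimmed with Trimmomatic, aligned with BWA 0.7.17 to mm10 and handled with SAMtools 1.10, per the submitters' processing notes, which name the tools without their order or settings. Peaks were called with HOMER in each library alone, not on pooled replicates, against the input of the same oxygen condition, per the file headers. The HOMER version is not given in the sources used here. Per the file headers, a peak needed 4-fold more tags than the input and than its local surroundings, each with a Poisson p of 1e-04. The peak size was 280 bp in normoxia PBS replicate 1 and 178 to 196 bp in the other 17 libraries. The headers' maximum of tags considered per base was 2 in normoxia PBS replicate 1 and 1 in the other 17.

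The deposited signal per peak is the authors' normalized tag count, scaled by the peak caller to 10000000 tags per library. This removes depth, but the counts of normoxia PBS replicate 1 were taken over a wider peak and with a higher cap per base than those of the other libraries. The input tags of a peak, also a deposited signal, are scaled to the library they were compared with, per the file headers. The deposited score per peak is the authors' peak caller score, which is not scaled to library size and was at least 50 in every list. The deposited fold over input is a ratio the authors' peak caller computed for each peak. Score and fold were used only to rank or filter peaks within a list. Because the minimum of 50 tags was not scaled, it stood for 11.5 normalized tags in the deepest library and 86.6 in the shallowest.

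Depth was 5772670 to 43645787 tags, and at most 16500568 without normoxia PBS replicate 1. Intervals of shares are 95% Wilson intervals and cover counting error only. No group held a pair of identical lists.

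Peaks of all 18 libraries that overlapped by at least 1 bp were merged into sites. A site's replicates are its detections, that is, the libraries whose list holds a peak there, and its tag count is the authors' normalized tag count of the highest peak in the site. Tag counts at a site were averaged over the libraries that detected it, which leaves out libraries below the caller's threshold. Sites detected in 3 or more of the 18 libraries were tested for DEX against PBS with an exact Cochran-Mantel-Haenszel test stratified by oxygen condition. Sites detected in 2 or more of 9 libraries were tested for hypoxia (6 h and 24 h together) against normoxia with Fisher's exact test, within DEX and within PBS. Both tests were two-sided, with Benjamini-Hochberg adjustment over the sites tested and a threshold of 0.05. Values per library (log2 numbers of peaks, the share of tags in peaks, the share of peaks near gene ends) were compared with exact two-sided permutation tests, DEX labels being permuted within oxygen conditions. Similarity of peak sets was the Jaccard index (shared sites over all sites of a pair of libraries) at equal list length, tested over the 280 partitions of the 9 DEX libraries into 3 groups of 3. Sites of a group were those in at least 2 of its 3 libraries.

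Genes came from a table of the GRCm38.p6 assembly, the assembly behind mm10. Each site was given to the nearest of 21883 protein-coding genes by the distance from its centre to the gene's span, 0 meaning inside, with the shortest gene taken where several hold it. Transcription start sites and exons were not used here, so this distance took the place of the distance to a start site, and a peak within 1 kb of either end of a gene's span took the place of a promoter peak. No genome sequence was used here, so the search for glucocorticoid response elements in peaks was not run. The 12 gene lists, written before the data were examined, were classical glucocorticoid-induced genes, gluconeogenesis and amino acid breakdown, fatty acid oxidation and ketogenesis, targets of hypoxia-inducible factors (HIF), circadian clock, acute phase and inflammation, bile acid, cholesterol and xenobiotic metabolism, liver transcription factors, and markers of Kupffer cells and leukocytes, endothelium, stellate cells and cholangiocytes, and hepatocytes. All their genes matched the table. A gene had a site if it was the nearest gene to one within 50 kb. Lists were tested with a one-sided Fisher's exact test against all other protein-coding genes, adjusted over lists and site sets, and again with 10000 random lists matched on gene span length. Sites near list genes were also adjusted over the list alone.

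The sites named in the text follow a rule set before the data were examined. For each comparison and direction these are the 12 sites with the largest difference in the share of libraries that detect them, ties going to the higher mean rank percentile of the authors' score. Where none passed, the same 12 are named and said not to pass. List genes are given as counts with the members detected in the most libraries as examples, joined by members with a gained site, which were chosen after seeing the data. A list member is not reported here.

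Some steps were chosen after seeing the data. The first was a threshold common to all libraries, 86.6 normalized tags. The second was limma 3.58.1 (R 4.3.3) on log2 normalized tag counts, for hypoxia against normoxia at sites called in all 9 DEX libraries, each library centred on its median, and for DEX against PBS, without centring and with the oxygen condition as a term, at sites called in all 18. At these sites the 12 with the largest log2 change past adjusted p 0.05 in each direction are named. A further step was leaving out normoxia PBS replicate 1. The length-matched lists and the fits with the share of tags in peaks as a covariate, with a block or without centring were added with them. Requiring a call in all libraries keeps sites that fell below the caller's threshold out of limma.

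Alternatives set beforehand were peaks at least 8-fold over input, equal list lengths, autosomes only, reducing peaks to 50 bp either side of the centre or widening them by 200 bp, leaving out each library in turn, a replicate block, a linear scale for numbers of peaks, all 3 or any 1 library per group, a gene-end window of 5 kb, and gene distances of 10 kb and 100 kb.

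The tests of sites were also run on simulated data, limma in the same run as its real fits. The tests of gene lists, of peak set similarity and of the difference in DEX effect were not. With 200 of 2563 sites detected with probability 0.9 with DEX and 0.1 with PBS, the stratified exact test recovered 48.5% and made 0 false calls. The real test called 1418 sites more often with DEX, so its adjusted threshold was looser. These rates therefore do not carry over to it. For hypoxia against normoxia with DEX, 200 of 2938 simulated sites with probabilities of 0.95 and 0.05 gave 0% recovered, since 6 against 3 libraries could not pass adjustment there. For tag counts, limma recovered 96% of 200 of 935 sites changed by a log2 of 1, with 5.88% false calls among its calls. The simulated noise was independent between sites, so deviations that many sites of a library share were not covered. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.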

Results

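Binding of the glucocorticoid receptor in mouse liver was measured by ChIP-seq in normoxia and after 6 h and 24 h at 7% oxygen, each with DEX or PBS, with 3 animals per group. The design asked how DEX changes the sites the receptor occupies and whether hypoxia changes that occupancy. Library depth was 5772670 to 13181686 tags with DEX and 8667179 to 43645787 with PBS. Tag counts at sites are the authors' normalized tags, per 10000000 tags of a library. Peaks per library numbered 2803 ± 754 (SD, n = 3 here and for the next 5 means) in normoxia with DEX, 1717 ± 391 after 6 h and 1631 ± 572 after 24 h of hypoxia with DEX. With PBS they numbered 1468 ± 2122 in normoxia, 534 ± 271 after 6 h and 164 ± 91.5 after 24 h. The peaks of all 18 libraries merged into 7398 sites, of which 4369 were found in 1 library, 935 in all 9 DEX libraries, 64 in all 9 PBS libraries and 62 in all 18.

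Normoxia PBS replicate 1 stood apart from the rest. It held 43645787 tags and 3915 peaks, against 145 and 343 peaks in the other normoxia PBS libraries, and 3232 sites were found in it alone. Of its peaks, 64.4% (95% Wilson interval 62.9 to 65.9) lay within 1 kb of a gene end, against 7.69% to 12.4% in the other 17 libraries. At a threshold of 86.6 normalized tags in every library it kept 28 peaks, while the other normoxia PBS libraries kept 91 and 93. Every value that rests on the normoxia PBS group includes this library unless said otherwise.

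**Figure D1:**
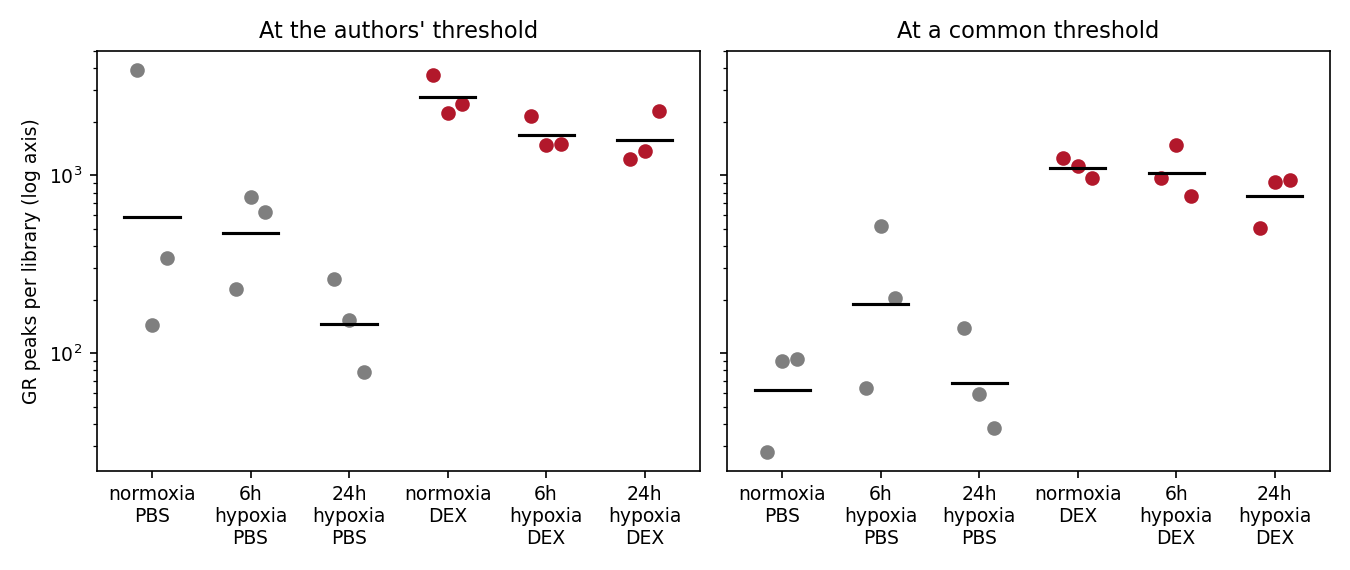
Number of GR peaks per library on a log axis, at the authors' threshold (left) and at a common threshold of 86.6 normalized tags (right), with points for libraries, bars for geometric means of 3, PBS in grey and DEX in red. At the common threshold the DEX libraries held 508 to 1484 peaks and the PBS libraries 28 to 516.

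DEX brought the receptor to sites at which PBS livers gave no peak. At 209 sites a peak was called in all 9 DEX libraries and in 0 of 9 PBS libraries. The highest ranking of these lay in Pag1, which encodes a membrane raft adaptor that binds the kinase Csk (chromosome 3, 9822069 to 9822312, mm10, 305 ± 107 normalized tags, SD, n = 9). The next lay 2761 bp from Agtpbp1, a tubulin-modifying carboxypeptidase gene (chromosome 13, 59446666 to 59446880, 474 ± 226). Another lay inside Hsd17b2, whose enzyme inactivates estradiol (chromosome 8, 117715963 to 117716171, 249.6 ± 53.9). Such sites were also found in Scarb1, which encodes the HDL receptor SR-BI (chromosome 5, 125297359 to 125297566, 251 ± 145), and in Ppard, the gene of the fatty acid-sensing nuclear receptor PPAR delta (chromosome 17, 28272320 to 28272546, 256 ± 162). The kinase genes Nek7 (259 ± 89.2) and Dapk1 (209 ± 70.6) each held such a site. So did Rnf169 (229.97 ± 55.6), Washc2 (226 ± 68.1), Nav2 (209 ± 67.4) and Iqch (195 ± 67.8). The last of the 12 lay far from any coding gene, 161413 bp from Gm46911 (175 ± 42.5).

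Of 2563 sites tested, 1418 were detected more often with DEX and 1 less often in the exact Cochran-Mantel-Haenszel test stratified by oxygen condition (two-sided). Each of the 12 sites above was detected in 9 of 9 DEX and 0 of 9 PBS libraries, with an exact p of 0.00025, the smallest the design can give, and an adjusted p of 0.00307. The site detected less often was mitochondrial (positions 15455 to 15744). It was called in 9 of 9 PBS libraries, but with DEX in 3 of 3 libraries after 24 h of hypoxia and 0 of 6 others. The share of libraries differed by -0.667, with an adjusted p of 0.0138 in the same exact test. Of the sites gained with DEX, 55.5% (Wilson 52.9 to 58.1) lay inside a protein-coding gene span, and the median distance of the remainder to the nearest gene was 12206 bp. With the replicate number as a further stratum 921 sites were called more often and the mitochondrial site no longer passed, and at the common threshold 757. At equal list lengths, with each list held to its 78 highest scoring peaks, 28 were called more often and 13 less often.

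The 62 sites called in all 18 libraries held known glucocorticoid-responsive genes and carried more tags with DEX. The largest change was at a site whose nearest gene span was that of Armc12 and which lay 26.8 kb from Fkbp5, the gene of a co-chaperone of the receptor (chromosome 17, 28512744 to 28513084). It held 1585 ± 280.1 normalized tags with DEX and 185 ± 211 with PBS (SD, n = 9 each), a log2 change of 3.69 ± 0.33 (SE). Sites in Cdkn1a, the p21 cell cycle inhibitor gene (log2 change 2.38 ± 0.32, 966 ± 174 against 234 ± 200.3 tags), and Nfkbia, which encodes an inhibitor of NF-kappaB (2.29 ± 0.31, 450.4 ± 71.6 against 112 ± 83.6), also rose. So did sites in the lipid droplet gene Plin4 (2.48 ± 0.33), in Foxp1 (2.56 ± 0.31) and in Hectd4 (2.26 ± 0.32), and a site 274 bp from Zfp36, whose product destabilises inflammatory messenger RNAs (2.05 ± 0.31). Farther out, sites rose 6099 bp from Ttpal (2.13 ± 0.32), 34007 bp from Gm5148 (2.47 ± 0.31), 78927 bp from Ptpn1 (2.68 ± 0.32) and 142658 bp from Irf2bp2 (2.06 ± 0.32). A site 51259 bp from Rxra, the gene of the shared partner of many nuclear receptors (2.03 ± 0.32), completes the 12 largest rises. Of the list genes, Nr1i2, the xenobiotic receptor PXR gene, rose by a log2 of 1.60 ± 0.31 and Klf9 by 1.39 ± 0.30. The site in the clock gene Per1 was an exception, with 439.6 ± 85.4 tags with DEX and 376 ± 133 with PBS (log2 0.30 ± 0.30). So was a site 66809 bp from Lpp with 285 ± 50.3 and 285 ± 84.6 tags (0.06 ± 0.30).

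With limma on these 62 sites, 59 rose past adjusted p 0.05 and 0 fell, also 0 at an unadjusted p under 0.05. The median log2 change was 1.63, and a site near Trim2 (0.60 ± 0.30) joined Per1 and Lpp in not passing. Without normoxia PBS replicate 1, 60 rose and the median was 1.49. The median tag count per library at these sites was 3.10-fold higher with DEX (exact permutation p = 0.0005, two-sided, 9 against 9 libraries within oxygen conditions). Normoxia PBS replicate 1 had the lowest such median, 46.8, against 154 and 131 in the other normoxia PBS libraries.

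**Figure D2:**
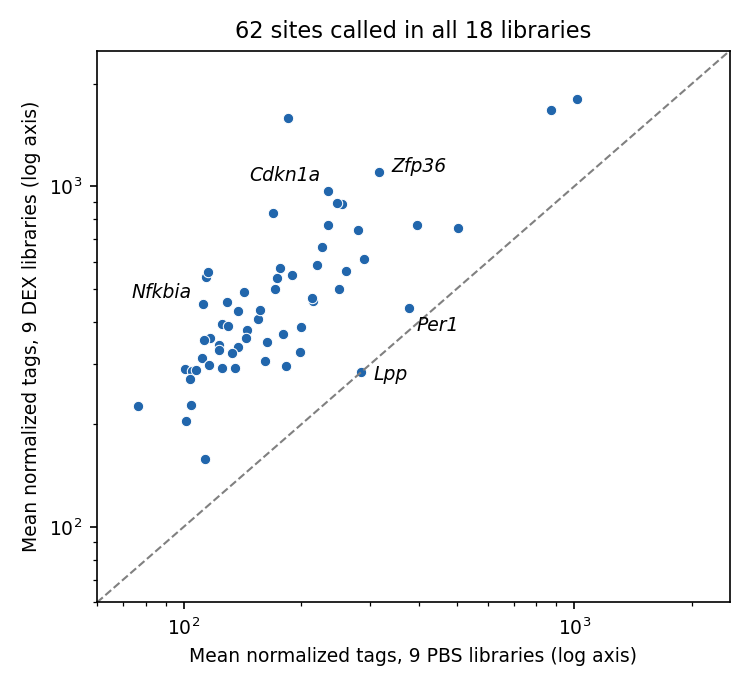
Mean normalized tag count with DEX against PBS, both on log axes, at the 62 sites called in all 18 libraries, with the dashed line marking equal values. Cdkn1a lies at 966 against 234 tags, while Per1 (439.6 against 376) and Lpp (285 against 285) lie close to the line.

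Genes of the metabolic and stress programmes of the liver were over-represented near the sites gained with DEX, relative to all protein-coding genes. Of 26 classical glucocorticoid-induced genes 14 had such a site (adjusted p = 1.1e-11, one-sided Fisher's exact test), against 4.52% of all 21883 protein-coding genes. Igfbp1 and Pik3r1 were bound at best in 16 libraries, while the best sites of Per1, Cdkn1a, Zbtb16, Klf9 and Nfkbia were called in all 18. Among genes of gluconeogenesis and amino acid breakdown 7 of 19 had a gained site (adjusted p = 4.5e-05). The transaminase gene Tat was bound at its best site in 9 DEX and 2 PBS libraries, with 157 ± 58.5 tags in the DEX libraries, and Got1 in 9 and 4 (211 ± 76.0 tags). The best sites of Pck1 and G6pc, which encode enzymes of glucose production, and of Cps1 were found in 15, 14 and 14 libraries and did not pass the test of detection, although G6pc had 1 other site that was gained. Pck1 held 124 ± 28.6 tags in 9 DEX libraries and 72.7 ± 24.6 in 6 PBS libraries.

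Of the acute phase and inflammation genes 10 of 24 had a gained site (adjusted p = 2.4e-07). Nfkbia was bound in all 18 libraries, followed by Orm1 (144 ± 20.7 tags in 9 DEX libraries), the interleukin-6 receptor gene Il6ra (121 ± 46.6) and the siderophore-binding protein gene Lcn2 (293 ± 64.5). Liver transcription factor genes numbered 6 of 16 (adjusted p = 0.00015), with Nr1i2 bound in all 18 libraries and Ppara, Hnf4a and Foxa3 in 9, 9 and 8 DEX libraries. Clock genes numbered 6 of 19 (adjusted p = 0.00043), with Per1 bound in all 18 libraries, Per2 in 15, and Ciart (283 ± 75.7 tags) and Tef (186 ± 50.2) in all 9 with DEX. Bile acid, cholesterol and xenobiotic genes numbered 5 of 18 (adjusted p = 0.0025), with the nuclear receptor gene Nr0b2, Insig2, Abcc2 and Srebf2 each bound in 9 DEX libraries. Genes of fatty acid oxidation and ketogenesis numbered 5 of 24 (adjusted p = 0.00859). Lpin1, a gene of lipid synthesis and fat oxidation, was bound in 17 libraries with 540.4 ± 150.2 tags in those given DEX, followed by the carnitine palmitoyltransferase gene Cpt1a at 149.5 ± 33.6 tags and Bdh1, an enzyme gene of ketone body metabolism, at 313 ± 110.0.

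Of 26 HIF target genes 4 had a gained site (adjusted p = 0.0464): Bnip3, a mitophagy gene (265 ± 65.4 tags in 9 DEX libraries, 58.7 ± 42.5 in 3 PBS libraries), Bhlhe40 (86.8 ± 14.8 with DEX), Pfkfb3 (124 ± 31.6) and Hmox1. The best site of Ldha, found in 11 libraries, did not pass. Among markers of other liver cells, 4 of 14 endothelial genes had one (adjusted p = 0.00676), namely Flt1, Vwf, Gpihbp1 and Stab2. The counts were 0 of 15 for Kupffer cell and leukocyte genes and 0 of 16 for stellate cell and cholangiocyte genes, too few genes to tell from the 4.52% of all genes, and their single sites, near Ptprc and Sox9, were found in 1 and 2 DEX libraries. The hepatocyte marker list did not pass with 2 of 15 (Alb and Glul, adjusted p = 0.215). All 9 lists that passed also passed against random lists matched on gene length, while at equal list lengths 1 list passed. Neither background was matched on expression or open chromatin in liver. Enrichment of a programme was therefore not told apart from that of genes active in liver.

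Counted by site, 25 of the 51 tested sites near classical glucocorticoid-induced genes were detected more often with DEX, and 24 adjusted over the list alone. The corresponding counts were 10 and 7 of 21 near gluconeogenesis and amino acid genes, 16 and 16 of 23 near acute phase genes, 8 and 8 of 12 near clock genes, and 8 and 8 of 14 near liver transcription factor genes. They were 7 and 7 of 16 near fatty acid oxidation genes, 6 and 6 of 14 near bile acid and xenobiotic genes, 6 and 6 of 11 near HIF targets, 4 and 4 of 6 near endothelial markers and 3 and 3 of 8 near hepatocyte markers.

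By library, DEX raised the number of peaks 5.66-fold (log2 difference 2.50, exact permutation p = 0.001, two-sided, 18 libraries). The log2 difference was 2.24 in normoxia (exact p = 0.4), 1.83 after 6 h of hypoxia (exact p = 0.1) and 3.43 after 24 h (exact p = 0.1), where 3 against 3 libraries cannot go below 0.1. Leaving out single libraries moved the normoxia value between 1.24 and 3.62 (exact p = 0.1 to 0.5), a range that holds the values of both other conditions. At the common threshold the log2 difference was 3.37 (exact permutation p = 0.00025), and 4.16 in normoxia, 2.45 after 6 h and 3.49 after 24 h (exact p = 0.1 each). The share of tags in peaks was 2.60% ± 0.687 with DEX and 0.453% ± 0.346 with PBS (SD, n = 9 each), a difference of 2.15 percentage points (exact permutation p = 0.00025, the smallest possible). The share of peaks near gene ends differed by -5.14 percentage points (exact permutation p = 0.920). The sign turned without normoxia PBS replicate 1 (0.906 points, exact p = 0.162), and at the common threshold it was 2.79 points higher with DEX (exact p = 0.001).

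With DEX, receptor signal differed between hypoxic and normoxic livers at a limited set of sites. Among the 935 sites called in all 9 DEX libraries, 19 held more and 13 fewer tags in hypoxia than in normoxia (limma, adjusted p 0.05, each library centred on its median). The largest rise was at a site 2359 bp from Gadd45b, a growth arrest and DNA damage response gene (chromosome 10, 80934453 to 80934674), which went from 61.0 ± 3.16 normalized tags in normoxia to 186 ± 101 after 6 h and 149.7 ± 8.73 after 24 h (SD, n = 3 each). Its log2 change was 1.54 ± 0.17 (SE, limma adjusted p = 9.1e-05). A site in Parva, which encodes a focal adhesion protein, rose from 88.0 ± 19.9 to 242.5 ± 93.9 and 209.7 ± 48.4 tags (chromosome 7, 112469938 to 112470194, log2 change 1.48 ± 0.15, limma adjusted p = 7.0e-05). The largest fall was in Ppard, from 456 ± 86.0 to 139 ± 41.8 and 173 ± 72.7 tags (log2 change -1.47 ± 0.21, limma adjusted p = 0.00149), followed by Scarb1, from 424 ± 63.2 to 199 ± 78.1 and 128 ± 52.1 (log2 change -1.33 ± 0.19, limma adjusted p = 0.00149). At these 4 sites all 6 hypoxia libraries lay beyond all 3 normoxia libraries.

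The other named rises were at a pair of sites in Gng7, a G protein subunit gene (log2 changes 0.93 ± 0.17 and 0.91 ± 0.20), and near the membrane repair gene Dysf (0.83 ± 0.15), Arrdc5 (0.81 ± 0.15), the tubulin gene Tubd1 (0.76 ± 0.18) and Tead1, a transcription factor of the Hippo pathway (0.75 ± 0.14). Tags also rose at Bdh1 (0.69 ± 0.17), Ppp1r14b (0.67 ± 0.15), Zc3h3 (0.65 ± 0.16) and Chrdl2 (0.62 ± 0.12). The other falls were at Stk4, a Hippo pathway kinase gene (-1.15 ± 0.26), Cdk17 (-1.11 ± 0.27) and Agtpbp1 (-1.10 ± 0.19, from 753 ± 62.3 tags to 367 ± 56.5 and 302 ± 139.5). Tags also fell at Tpst2 (-0.87 ± 0.16), Srebf2, the regulator of cholesterol synthesis (-0.86 ± 0.19), and the kinase gene Map3k1 (-0.78 ± 0.16). Falls were also found at Rab11fip4 (-0.72 ± 0.16), Slc25a51, a mitochondrial NAD carrier gene (-0.71 ± 0.18), and a pair of sites in the peptidase gene Dpp9 (-0.64 ± 0.16 and -0.60 ± 0.15). These changes take 6 h and 24 h together, and some were uneven in time. Tubd1 rose by 0.98 ± 0.17 after 6 h and 0.53 ± 0.17 after 24 h, and Bdh1 by 0.89 ± 0.16 and 0.48 ± 0.16. Stk4 changed by -0.76 ± 0.23 and -1.55 ± 0.23, and Cdk17 by -0.71 ± 0.24 and -1.50 ± 0.24. A difference between the times was not tested. After centring each library on its median, all 6 hypoxia libraries lay beyond the 3 normoxia libraries at 18 of the 19 higher and 12 of the 13 lower sites, the exceptions being Tubd1 and Cdk17 with 5 of 6. In normalized tags without centring they did so at 5 higher and 9 lower sites, and at least 4 of 6 did at the others.

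Of the list genes, those with a changed tag count were Bdh1 (fatty acid oxidation and ketogenesis, 1 of 6 sites) and Srebf2 (bile acid, cholesterol and xenobiotic metabolism, 1 of 5 sites), and the same 1 site each passed adjusted over the list alone. In the remaining lists 0 sites passed in limma over all sites or adjusted over the list alone, among them 33 sites near classical glucocorticoid-induced genes and 3 near HIF targets. Over all 935 sites, 136 had an unadjusted limma p under 0.05. Hypoxia DEX libraries had a lower share of tags in peaks by -0.791 percentage points (exact permutation p = 0.131), and with that share as a covariate limma called 4 sites, at Gadd45b, Parva, Ppard and Scarb1. Without centring, which shifted the median log2 change over all 935 sites from 0.05 to -0.10, it called 2 higher and 9 lower, and leaving out normoxia DEX replicate 2 left 3 and 2.

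**Figure D3:**
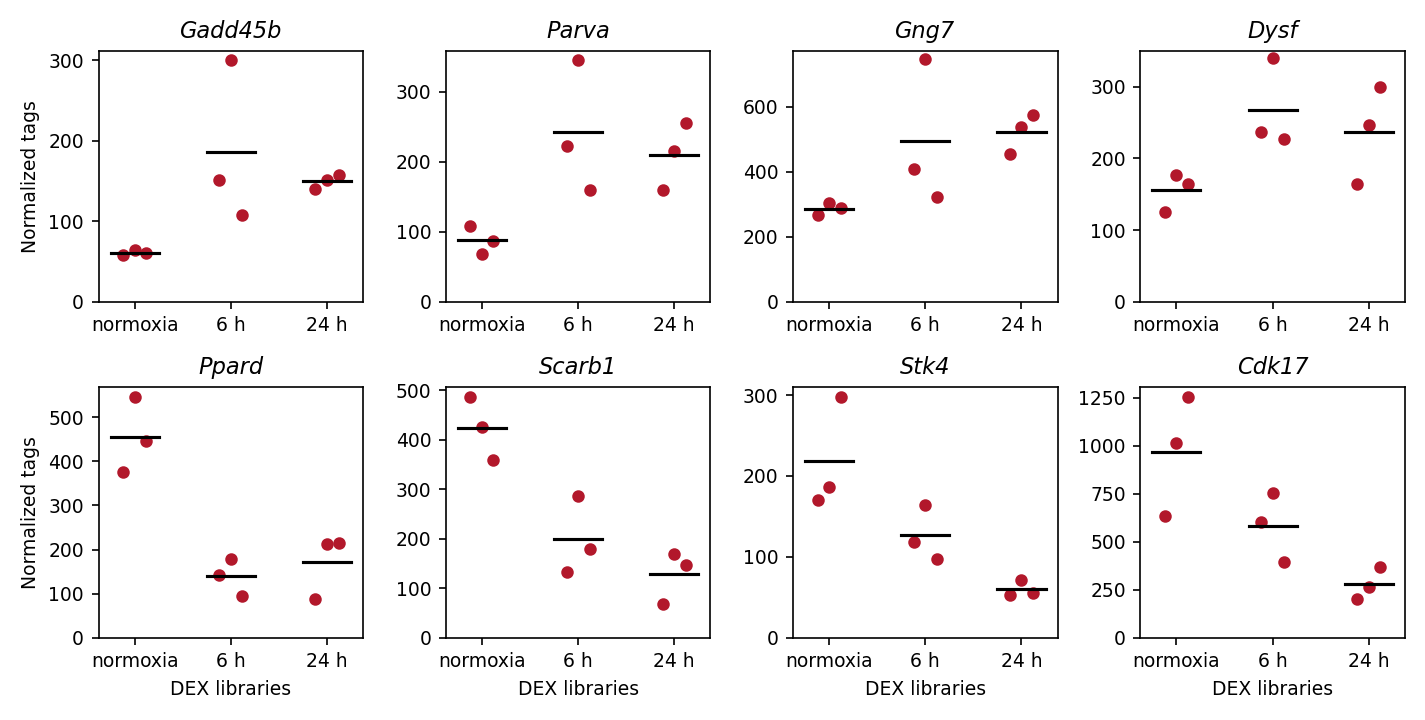
Normalized tags in each DEX library at the 4 genes with the largest rises (upper panels, Gng7 by its first site) and the largest falls (lower panels) in hypoxia, with bars for means of 3. At Gadd45b the normoxia mean was 61.0 and the 24 h mean 149.7, and at Ppard the means were 456 and 173.

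At 102 further sites, none of which passed a test of detection, a peak was called in all 3 normoxia DEX libraries and 0 of 6 hypoxia DEX libraries. The highest ranking lay at the dynein light chain gene Dynlrb1 (173 ± 38.3 tags, n = 3). Others of the 12 lay at Acsl1, which activates long-chain fatty acids (123 ± 29.5), at the ferritin receptor gene Scara5 (98.0 ± 12.2) and near the choline kinase gene Chka (75.5 ± 9.1). The remaining ones were in Map4k3, Fam71e1, Ttc39c and Itsn1, near Mknk2 and Kctd17, 28829 bp from Cpeb4 and 53637 bp from Caprin1. Means at the Chka, Mknk2 (85.5), Kctd17 (78.4), Itsn1 (76.1) and Caprin1 (73.9) sites lay below 86.6 tags already in normoxia. The sites called most often in hypoxia instead were in Gng7 (5 of 6 hypoxia and 0 of 3 normoxia libraries, 83.8 ± 32.8 tags), Tsku (5 of 6, 76.1 ± 26.0) and Rexo5 (5 of 6, 75.7 ± 28.3). Sites in Rbms2 and Tmem189, near Ndufa6 and Lhpp, and 240706 bp from Wdr11 were called in 4 of 6 and 0 of 3. A site near Arrdc2 and the mitochondrial site were called in 3 of 6 and 0 of 3. Those at Hamp, the hepcidin gene, and the endothelial gene Stab2 were called in 5 of 6 and 1 of 3.

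In Fisher's exact test (two-sided) on 2938 sites, 0 passed in either direction, with 257 less often and 3 more often at an unadjusted p under 0.05. The smallest exact p that 6 against 3 libraries allow is 0.0119, and the smallest adjusted p was 0.343 at a difference of all 3 against 0 of 6. At the common threshold, 38 of 1368 sites were less often and 1 more often detected at an unadjusted p under 0.05.

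The DEX libraries of hypoxic livers held 1.68-fold fewer peaks than those of normoxic livers (log2 difference -0.75, exact permutation p = 0.0476, two-sided, 6 against 3 libraries). The log2 difference was -0.70 after 6 h (exact p = 0.1) and -0.80 after 24 h (exact p = 0.2), against a smallest possible 0.1. The call was lost at the common threshold (-0.32, exact p = 0.333), with replicate blocks (-0.75, exact p = 0.0741) and without any of 6 of the 9 libraries, with exact p of up to 0.107. At the 935 shared sites the median log2 tag count per library differed by -0.15 (exact permutation p = 0.512). The share of peaks near gene ends differed by -1.15 percentage points (exact permutation p = 0.155).

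Most sites of hypoxic livers given DEX were also sites of normoxic ones. Of 2551 normoxia DEX sites, 61.4% (Wilson 59.5 to 63.3) were also sites of 6 h hypoxia with DEX and 54.8% (52.9 to 56.7) of 24 h. Conversely 94.5% of 1659 sites of 6 h hypoxia with DEX and 96.1% of 1455 of 24 h were normoxia DEX sites. Classical glucocorticoid-induced genes with a site numbered 21 of 26 in normoxia, 19 after 6 h and 21 after 24 h with DEX. HIF targets numbered 7, 5 and 4 of 26, while the share over all genes was 7.29%, 5.12% and 4.50%. With DEX, 10 of the 12 lists passed in each oxygen condition, 9 in normoxia against length-matched lists. At an equal length of 1235 peaks, DEX libraries of the same oxygen condition had a mean Jaccard index of 0.715 and those of different conditions 0.673, a difference of 0.0424 (permutation p = 0.0107 over 280 partitions). Within conditions the index was 0.681 ± 0.0491 in normoxia, 0.702 ± 0.0538 after 6 h and 0.762 ± 0.0172 after 24 h (SD, 3 pairs each). Without any one of the 24 h DEX libraries the permutation p was 0.05 to 0.0786.

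**Figure D4:**
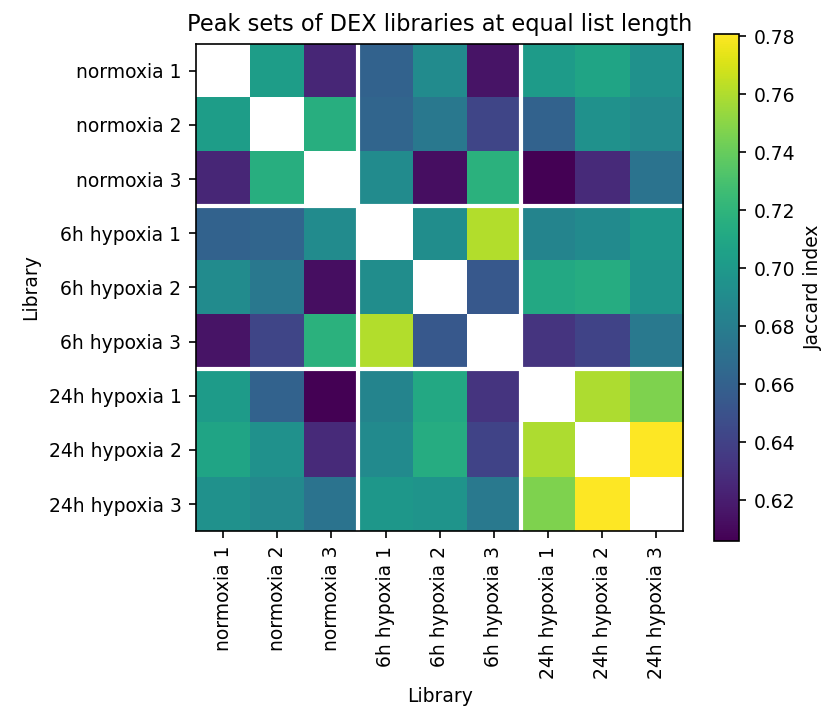
Jaccard index of the peak sets of each pair of DEX libraries, each list taken at its 1235 highest scoring peaks, with white lines between oxygen conditions. The 3 pairs of 24 h libraries lie between 0.747 and 0.781, and pairs of normoxia libraries between 0.625 and 0.715.

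Without DEX, fewer sites were shared by libraries of a group, and most of them were sites that DEX also filled. 6h hypoxia PBS replicate 2 stood apart from the other PBS libraries, with a median of 375 normalized tags at the 62 sites called in all libraries, inside the range of the DEX libraries (287 to 545). It kept 516 peaks at the common threshold, against 508 in 24h hypoxia DEX replicate 1. Sites of the PBS groups numbered 286 in normoxia, 507 after 6 h and 151 after 24 h, and 92.0%, 95.7% and 96.0% of them were sites of the DEX group of the same oxygen condition. Without 1 library of the group, where a site needed both others, they numbered as few as 140, 205 and 71. Classical glucocorticoid-induced genes had a PBS site in 10 of 26 cases in normoxia, 14 after 6 h and 6 after 24 h. Of the 12 lists 5, 6 and 1 passed, the single one after 24 h being this list, and without 1 library as few as 3, 2 and 1. Gluconeogenesis and amino acid genes numbered 5 of 19 in normoxia, 8 after 6 h and 0 after 24 h. The share of all genes with a PBS site also moved, being 1.02%, 1.70% and 0.516% in the same order. The site called most often in hypoxia but not in normoxia with PBS lay in Hif3a, a member of the HIF family (chromosome 7, 17058230 to 17058437), found in 3 of 3 libraries after 6 h, 2 of 3 after 24 h and 0 of 3 in normoxia, and in 9 of 9 DEX libraries with 630.4 ± 126 tags.

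Sites near Ifngr2 and Dysf and in the heme synthesis gene Alas1 and the ubiquitin protease gene Usp2 were found in 4 of 6 hypoxia and 0 of 3 normoxia PBS libraries. Those in Map2k6, Mtss1 and Znhit1, near Gm51791 and the clock gene Ciart, and on an unplaced sequence were in 3 of 6 and 0 of 3. A further one on the same sequence was in 5 of 6 and 1 of 3. In the other direction, sites far from a coding gene were found in 1 of 6 hypoxia and 3 of 3 normoxia libraries. They lay 72523 bp from Ly6l and 51642 bp from the glutathione synthesis gene Gclc. Sites in Myo1e and near the urea cycle gene Cps1 and Cyp2b19 were in 2 of 6 and 3 of 3. Those in Pank1, Gpt2, Duxf3, Tpst2 and Hccs, 63553 bp from Cldn5 and 23465 bp from Actb were in 0 of 6 and 2 of 3. The normoxia group here includes normoxia PBS replicate 1.

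None of these differences passed. In Fisher's exact test on 632 sites 0 passed in either direction, with 1 more often and 2 less often at an unadjusted p under 0.05. The number of peaks with PBS differed between hypoxia and normoxia by a log2 of -1.14 (exact permutation p = 0.381, two-sided, 6 against 3 libraries). The difference was 0.24 without normoxia PBS replicate 1 (exact p = 0.857) and 0.87 at the common threshold (exact p = 0.417). The effect of DEX on the number of peaks differed between hypoxia and normoxia by a log2 of 0.39 (exact permutation p = 0.781), or -0.99 without normoxia PBS replicate 1 (exact p = 0.326). At the 62 sites called in all libraries the effect of DEX on the median tag count differed by a log2 of -0.72 (exact permutation p = 0.300).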

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

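Alternatives chosen after seeing the data were the common threshold, the fits without centring and with the covariate, length-matched gene lists and the added fits without normoxia PBS replicate 1. Over the results that answer a comparison, 332 values kept their direction and side of the threshold, or moved by less than 1.5 times for counts. Beside them 14 counts moved further, 8 values turned sign, 11 lost their call and 1 gained one. The effect of DEX on the number of peaks kept its direction and side of the threshold under every alternative (log2 2.17 to 2.96 when libraries were left out). So did its effect on the share of tags in peaks and the 0 counts for detection in hypoxia. With 6 against 3 libraries, however, sites pass adjustment only where many differ fully between the groups. The 102 that did so with DEX were too few.

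The fall in peaks in hypoxia with DEX was -0.32 at the common threshold (exact p = 0.333) and -0.90 to -0.54 when libraries were left out (exact p = 0.0179 to 0.107). With PBS, hypoxia against normoxia turned to 0.87 at the common threshold and ran from -2.14 to 0.24 without single libraries, the highest without normoxia PBS replicate 1. The difference in DEX effect turned to -10.8 peaks on a linear scale and -1.19 at the common threshold. It ran from -0.99 (without normoxia PBS replicate 1) to 1.39. The share of tags in peaks in hypoxia with DEX differed by -0.954 to -0.514 points, passing without 6h hypoxia DEX replicate 2 (exact p = 0.0357). The share of peaks near gene ends, DEX against PBS, was 0.427 points at equal list lengths and 2.79 at the common threshold. It ran from -8.45 to 0.906, the highest without normoxia PBS replicate 1. The similarity difference ran from 0.0286 to 0.0584, with a permutation p of 0.05, 0.0714 and 0.0786 without single 24 h DEX libraries. The cause of these shifts was not tested beyond the explanations weighed in the other observations.

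Sites detected more often with DEX numbered 28 at equal list lengths, where all lists were shortened to the smallest, and 757 at the common threshold, and gene lists near them numbered 1 at equal lengths. Sites detected less often numbered 13 at equal lengths and 0 on autosomes, which leave out the mitochondrial site. Higher tag counts in hypoxia numbered 2 without centring, 2 with the covariate, and 3 (without normoxia DEX replicate 2) to 24 without single libraries, with 10 without 6h hypoxia DEX replicate 1. Lower ones numbered 2 with the covariate, 7 at the common threshold, where fewer sites were tested, and 2 (without normoxia DEX replicate 2) to 13. The Stab2 site, called more often in hypoxia with DEX, reversed to -0.167 at the common threshold (chromosome 10, 86923603 to 86923877, difference in share of libraries). Of the named tag count sites, 98 values fell short of the threshold under an alternative, with the same direction, and 299 stayed.

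Taken over all groups together, replicate numbers showed little pairing of the libraries. Deviations from group means correlated at a mean r of 0.0117 over 45 pairs of the same number (10 above 0.1) and -0.00602 over the others, and 7 of 18 libraries correlated best with one of their own number. Between normoxia DEX and 6h hypoxia DEX, however, all 3 pairs of the same number lay above 0.1 (0.126, 0.181 and 0.146). Same-number pairs of 6h hypoxia PBS gave 0.224, 0.119 and 0.0439 with 6h hypoxia DEX and 0.145, 0.0815 and 0.0421 with normoxia DEX. Those of 24h hypoxia PBS and 24h hypoxia DEX gave 0.135, 0.00957 and 0.194. Normoxia DEX gave -0.0396, 0.0217 and 0.0137 with normoxia PBS, and -0.0875, 0.0874 and -0.0162 with 24h hypoxia DEX. A pairing of some groups, DEX with PBS in hypoxia among them, therefore stays open. With the replicate block the fall in peaks in hypoxia with DEX was -0.75 (exact p = 0.0741), sites detected more often with DEX numbered 921 and less often 0, and tag counts gave 25 higher and 15 lower, holding all 32 called without it. The search for glucocorticoid response elements, its looser pattern and its narrower window were not run, since no genome sequence was used. Depth sets which peaks pass 50 tags, from 11.5 to 86.6 normalized tags.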

Other observations

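The tests on normoxia PBS replicate 1 other than its tag count, those on the fewer peaks in hypoxia, that on neighbouring sites and those on the input at higher and lower sites apart were chosen only after the result was seen.

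Some sites whose tag counts changed in hypoxia with DEX lay close to each other. On chromosome 10 the Gadd45b site (80934453 to 80934674) rose together with a pair in the G protein gene Gng7 (from 80991497 to 80994946), and on chromosome 7 the Parva site (112469938 to 112470194) rose with one near Tead1 (112644717 to 112644950). A pair near Gm51791 also rose, and the pair in Dpp9 on chromosome 17 fell (56208809 to 56211394), while a site near Arrdc5 (56292972 to 56293193) rose beside it. In all, 10 of the 32 changed sites had another within 200 kb, forming 6 pairs called in the same direction, of which 3 were 2 sites nearest to a single gene, and 2 pairs in opposite directions. Whether neighbouring sites change together stays open, since these 6 pairs prompted the test and cannot also bear it out.

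Further sites that rose and lay outside the named 12 included one in Csf1, the macrophage growth factor gene (log2 change 0.59 ± 0.13, 64.8 ± 4.55 normalized tags in normoxia, 100.1 ± 20.2 after 6 h and 79.2 ± 14.6 after 24 h, SD, n = 3 each). Others lay in Gne, the gene of the key enzyme of sialic acid synthesis (0.61 ± 0.15), and near the endothelial gene Egfl7 (0.53 ± 0.12), and Pitpnm2 fell (-0.54 ± 0.14). They were chosen after their values were seen. Of the 13 sites that fell, 7 had no peak in any PBS library, against 1 of the 19 that rose. Zbtb16, a transcription factor gene of the classical glucocorticoid list, had 11 sites, of which 4 were detected more often with DEX.

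Behind the changed tag counts in hypoxia, a chance split of the libraries was argued against but not excluded. Of the 84 splits of the 9 DEX libraries, 1 gave as many as 32 calls, the real one. That is the smallest share 84 splits allow, and limma was chosen after seeing the data. The highest of the others gave 19, parting the 24 h DEX libraries from the rest. Uneven enrichment would have shrunk the changes under the covariate, whereas the median ratio of log2 changes with and without it was 0.957. It was not excluded, since this share depends on each library's own peaks at an unscaled threshold. The ratio also covers only sites called without the covariate. The fall to 4 calls went with wider errors, since the median SE of the higher sites rose from 0.15 to 0.18 and that of the lower sites from 0.18 to 0.21. The summed input tags moved by a log2 of 0.0713 in the direction of the receptor signal, but this joins opposite parts, -0.0777 at the higher sites (95% bootstrap interval over sites -0.491 to 0.407) and 0.289 at the lower sites (0.00289 to 0.546), against median absolute changes of 0.67 and 0.86. Local copy number or mapping therefore stays open, and an effect of hypoxia on these sites was not told apart from it.

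The extra peaks of normoxia PBS replicate 1 were weighed next. Its 28 peaks at the common threshold, below 91 and 93, are in line with depth under an unscaled threshold, and the 74.9% (Wilson 73.4 to 76.3) of its own sites that lay near gene ends are in line with background enrichment there. Its mean Jaccard index with the normoxia DEX libraries was 0.153, where the lowest of any DEX pair was 0.607 (each list at 1235 peaks, merged into sites together with this library). Peaks found in it alone, 82.6% of its list, would lower that index under either label. The index therefore does not decide whether it was a DEX library under a PBS label. More receptor at shared sites in this animal was argued against by its median of 46.8 normalized tags, the lowest of the group although counted over a wider peak.

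The fewer peaks of hypoxic DEX livers may follow in part from depth with a fixed tag threshold. The log2 difference shrank from -0.75 to -0.32 at the common threshold. That threshold was set by 6h hypoxia DEX replicate 2, the shallowest library, which kept 1484 of its 1485 peaks. Geometric means there were 1106 peaks in normoxia, 1029 after 6 h and 761 after 24 h with DEX. The 24 h libraries kept 508 to 944 peaks, all below normoxia (964 to 1249), at 8849180 to 12642344 against 10476853 to 13181686 tags. Depth was therefore not shown to account for the fall after 24 h. A general drop in tag counts at shared sites remains open, with a difference of -0.15 in the median log2 tag count (exact permutation p = 0.512). Lower tag counts on every shared site were argued against, since limma without centring called 2 sites higher, at Gadd45b (log2 change 1.39) and Parva (1.33). A smaller set of occupied sites in hypoxia cannot be told apart from these, since the numbers of peaks at the common threshold overlap and 9 libraries are few. That overlap rests on 6h hypoxia DEX replicate 2 alone (1484 peaks). The other hypoxia DEX libraries kept 508 to 962 peaks, against 964 to 1249 in normoxia.

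Other splits of the libraries bear on the remaining counts. For the 1418 sites detected more often with DEX, 1 of 100 splits, the real one, gave as many, and the highest other gave 0, which argues against chance. At the 62 sites called in all 18 libraries, 2 of 100 splits gave 59 calls, the real one and another that kept 7 of the 9 DEX libraries together. A count so near its ceiling does not part these splits, and the comparison rests on the median tag count per library (exact permutation p = 0.0005). For the 257 sites at an unadjusted p under 0.05 that were less often detected in hypoxia with DEX, 1 of 84 splits gave as many and the highest other gave 191. Chance was argued against for that count but not excluded. At the common threshold the count was 38 of 1368 tested sites, and the cause of the high count in another split was not tested. For sites more often detected in hypoxia with PBS, 30 of 84 splits gave as many as the real 1, and the highest other gave 61, so chance was not excluded.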
